A study of Mus musculus with 18 samples.

How the data were processed

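RNA was measured in double-positive (DP), CD4 single-positive (CD4 SP) and CD8 single-positive (CD8 SP) thymocytes sorted from C57Bl/6N wild-type mice (wt) and from mice in which FoxN1-Cre removed exon 3 of Gpr177 (cKO). The gene Gpr177 is now named Wls. FoxN1-Cre acts in thymic epithelium, so the deleted cells were not the cells on the arrays. The mice were 4 to 6 weeks old. Each of the 6 groups had 3 arrays, 18 in all, hybridized with biotin-labelled cRNA from 200 ng of RNA on Illumina mouse BeadChips.

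The deposited bead file gave a mean intensity per probe and array, on a linear scale and without subtraction of background. Beside it stood a deposited detection p-value per probe and array. How the detection p-value was computed is not given in the sources used here, nor is the scanner software. The detection p-values fell to values far too small for a rank among control probes, and their rank correlation with the intensity was between -0.995 and -0.992. The series matrix held an intensity on a linear scale, normalized between arrays by the authors with a method not given in the sources used here. Its array medians lay between 192.0 and 202.2, and each array correlated with its deposited bead intensities at 0.9997 or more. It entered only as an alternative source of values.

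Intensities were background-corrected with the detection p-values, quantile normalized and put on a log2 scale (neqc, offset 16) in limma 3.58.1 under R 4.3.3. Figures were drawn with matplotlib 3.10.9. Of 46237 probes, 26676 had a detection p-value under 0.05 on at least 3 arrays and were tested. Probes were named from the array's annotation, which gave 1 gene symbol for 35784 probes and none for 10453. The tested probes stood for 12978 genes. A gene was represented by its tested probe with the highest mean log2 value. Other probes that pointed the other way are mentioned for named genes past the threshold and for Wls within populations. For other genes without a call such probes were mostly not mentioned. Where no array of a group detected the probe, the difference is only a bound. The bound, written as "at least", is the fold between the mean of the group with detection and the other group with each value raised to the lowest detected value of its array.

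All 18 arrays entered one linear model with a mean per group, which left 12 residual degrees of freedom. Moderated t-tests in limma compared cKO with wt in each population and over the mean of the 3 populations, and compared the wt populations with each other. A moderated F-test covered the genotype by population interaction. P-values were adjusted over all tested probes (Benjamini-Hochberg), and 0.05 was the threshold. Errors printed after ± are standard errors of a difference, or standard deviations of 3 arrays after a group mean.

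Gene lists were tested with camera in limma (correlation between genes 0.01, 1 probe per gene), adjusted over the 24 lists with at least 4 measured genes. A second run estimated the correlation from the data, and fry was a further test. The 26 lists held 423 genes, of which 287 were measured. They covered WNT target genes (15 of 24 measured), WNT secretion, receptor and signalling components (23 of 34), DP stage (13 of 15), positive selection and T cell receptor signals (16 of 19), apoptosis and p53 (19 of 23), SP maturation and egress (20 of 25), CD4 lineage (5 of 8), CD8 lineage (9 of 14), regulatory T cells (9 of 14), NKT and innate-like T cells (10 of 20), gamma delta T cells (5 of 12), interferon-stimulated genes (29 of 35), glucocorticoid response (14 of 16), immediate early and heat shock genes (15 of 20), cell cycle (29 of 32), glycolysis (11 of 15), cholesterol synthesis (11 of 18), Notch targets (6 of 10), double-negative (DN) thymocytes (6 of 11), thymic epithelium and stroma (11 of 21), macrophages and dendritic cells (10 of 20), B cells (7 of 12), erythroid cells (4 of 13) and sex-linked genes (4 of 5). Neutrophil genes (1 of 10) and the substrain gene Nnt were too few to test. The groups, comparisons, tests, lists, thresholds and most alternatives were fixed before the data were examined.

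Genes were named by a fixed rule. Wls came first. Next came the genes past the threshold with the largest change and 3 values on one side of the other group's 3, or, where too few passed, the genes with the smallest p, said to miss the threshold. Names that are only clone or locus numbers were left out. From each list every member past the threshold is named if there are 4 or fewer, otherwise the 4 with the smallest p. Members whose call ended when 1 array was left out are counted with their list, and most of them are not named. Every gene said to have risen or fallen between populations differed in that direction on all 3 chips.

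Per the file headers, the label numbers 1 to 3 stand for 3 BeadChips, each with all 6 groups at the same 6 positions. Residuals of arrays with the same number and genotype correlated with a median of 0.089 over 18 pairs. The 3 pairs of cKO number 2 (0.163 to 0.194) and of cKO number 3 (0.229 to 0.314) were all above 0.1. Pairs on the same chip from the other genotype had a median of -0.00067 over 27 pairs, and pairs from different chips -0.016 over 90. The similarity thus lay with genotype and number together and not with the chip. A fit with the chip as a block, the same as a replicate block, and a fit with genotype and number as a random block (correlation 0.111) were run beside the unblocked one. Each found 1 probe for cKO against wt in DP, as did the unblocked fit. Each group kept one chip position, so group and position cannot be separated. The labels do not say whether replicates are separate animals, so the p-values measure the spread between these samples, which may be technical.

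Alternatives were no background correction, normexp with offset 50, median scaling, no filter on dim probes, a strict filter (detection p-value under 0.01 on at least 6 arrays), the series matrix values, trend and robust variance, array weights, blocks, only the arrays compared, and leaving out each array. The fit without the 3 cKO arrays of number 3 and the fit with the background level as a covariate were added after the arrays had been compared. The background level of each array lay close to its median intensity. It was 154.3 beside 161.5 in DP wt number 1, and 263.7 beside 273.2 in CD8 SP cKO number 1. A fit with this covariate therefore cannot part background from the overall intensity of an array.

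The median intensity per group ran from 169.0 ± 23.0 (DP wt) to 253.0 ± 35.1 (CD8 SP cKO), and the mean share of detected probes per group from 43.1% to 44.8%. The median standard error of a log2 difference was 0.37 within a population and 0.21 for the mean of 3. The pipeline was tested on simulated data with 200 of 26676 probes changed. At a log2 change of 1 it recovered 0% in DP, 0% in CD4 SP, 7.5% in CD8 SP and 62.5% for the mean. At 2 it recovered 73%, 67%, 76% and 98.5%, and at 0.58 none. For the wt populations it recovered at most 4.5% at 1 and at least 68.5% at 2, and for the interaction 36% at 2. The real wt comparisons called 912 to 2231 probes, more than the 200 changed in the simulation, so these shares may understate recovery there. Between wt CD4 SP and wt DP, 1429 of the 1608 called probes changed over 2-fold, so some calls lay under a log2 change of 1. With the 29 cell cycle genes shifted by 0.2 in DP, the list was called in 16 of 20 simulations, by 0.4 in 20 and by 0 in none. The simulations drew each gene independently, so they do not measure calls that arise where the genes of a list vary together. They also drew each array independently, although arrays of the same genotype and number correlated, so the recovery for the mean may be overstated.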

Results

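Arrays grouped by sorted population. Replicate arrays correlated at 0.848 to 0.908 on the log2 scale, and any 2 arrays at 0.755 or more. The first 3 principal components held 21.96%, 14.3% and 10.7% of the variance. The first parted DP from the SP populations (mean scores of wt arrays -70.9 for DP, 10.3 for CD4 SP and 32.7 for CD8 SP). The cKO means lay to the same side of their wt means in each population (-41.9, 30.4 and 39.4). The cKO arrays of number 3 did not share this in CD4 SP (12.3 against 23.3 in wt number 3) or CD8 SP (23.4 against 35.2). Mean median intensity was also higher in cKO than in wt in each population. It was 181.6 against 169.0 in DP, 220.1 against 172.8 in CD4 SP and 253.0 against 221.1 in CD8 SP. The shift on this component can therefore not be ascribed to genotype alone. Of the probes for the sorting markers, both for Cd4 and 2 of 3 for Cd8b1, the beta chain of the CD8 coreceptor, followed the labels. The brightest Cd8b1 probe averaged 11.69 in wt DP, 10.91 in wt CD8 SP and 7.87 in wt CD4 SP, while another was higher in wt CD4 SP (8.04) than in wt CD8 SP (7.31) and wt DP (5.81). The Cd4 probe that stands for the gene averaged 8.46, 7.69 and 6.71 in wt DP, CD4 SP and CD8 SP and was detected on all these arrays, and the other averaged 8.76, 8.45 and 4.44. The tested Cd8a probe was detected on 2 of 3 wt DP arrays (6.51 and 6.08), on 1 wt CD4 SP array (5.86) and on no CD8 SP array, and Zbtb7b and Runx3 were not measured.

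**Figure D1:**
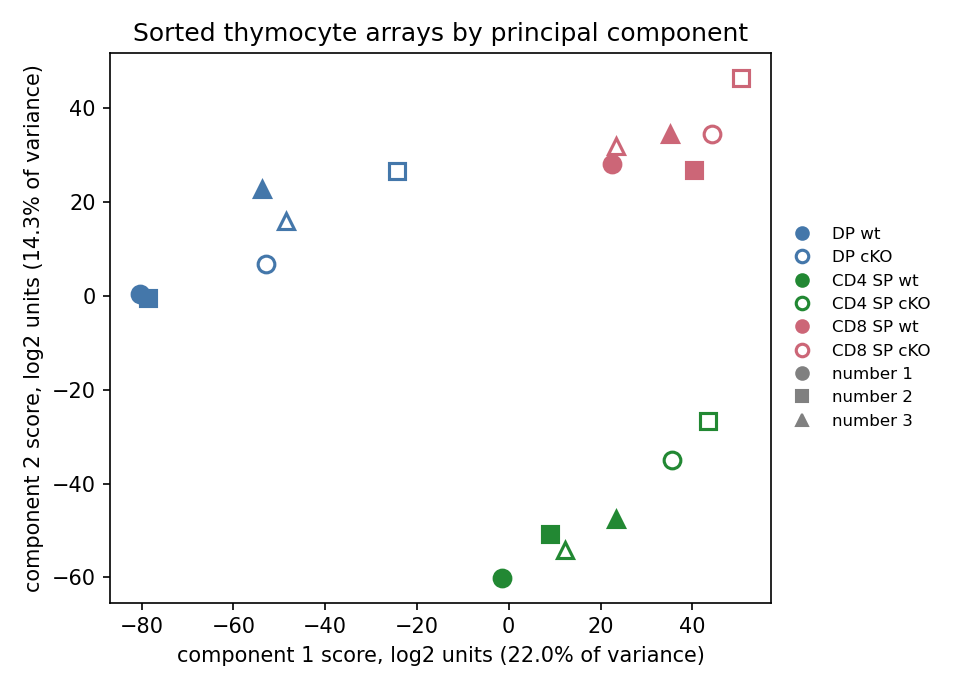
Scores of the 18 arrays on the first 2 principal components of log2 values (21.96% and 14.3% of the variance). Colours give the population, filled points wt and open points cKO, and shapes the label number; the mean wt score on component 1 was -70.9 in DP, 10.3 in CD4 SP and 32.7 in CD8 SP.

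In DP thymocytes, cell cycle genes as a group were lower in cKO than in wt by camera with a preset correlation. The call was lost with an estimated correlation (camera adjusted p = 0.757) and in fry. The members with the smallest p were Aurkb, a kinase of chromosome segregation, and Ccne2, a cyclin of S phase entry. No gene with a symbol passed the test by itself. Wls, which carries WNT proteins to the cell surface and was deleted in the epithelium only, was detected in all 3 arrays of every sorted group. Its DP values were 6.80 ± 0.33 in cKO and 5.89 ± 0.61 in wt (log2 difference 0.91 ± 0.31, limma adjusted p = 0.437). The differences on the 3 chips were 0.64, 0.58 and 1.51, while 2 other Wls probes gave 0.02 and -0.08.

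One probe passed in DP, ILMN_1251826, which has no gene in the annotation. It averaged 6.24 ± 0.23 in wt, where all 3 arrays detected it, and 4.40 ± 0.12 in cKO, where none did (limma adjusted p = 0.00998, 0.0328 with the chip as a block). Leaving out DP wt number 1, 2 or 3 or DP cKO number 2 or 3 left 0 probes past the threshold, and leaving out DP cKO number 1 gave 2. At an unadjusted p under 0.05 limma counted 2292 probes (1194 higher, 1098 lower), where chance gives 1333.8. Named genes that missed the threshold were, among those higher in cKO, Adam23 (1.60 ± 0.34, limma adjusted p = 0.197), Fbh1 (1.33), Sox14 (1.10), V2r1 (1.49) and Alg6 (1.30). Among those lower were Akr1b10, an aldo-keto reductase (-1.73 ± 0.30, limma adjusted p = 0.0935), Kcnq5, a potassium channel (-2.21 ± 0.42, limma adjusted p = 0.126), Anln (-1.32), Rsrp1 (-1.08) and Gnpda2 (-1.75). Akr1b10 had a limma adjusted p of 0.0279 without DP cKO number 1, within 0.0279 to 0.608 over 31 alternatives. Rsrp1 had 0.0332 with no filter, within 0.0332 to 0.685 over 28.

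Of the 29 measured cell cycle genes, 21 were lower in cKO DP cells (median log2 -0.11), and the mean shift was -0.21, -0.17 and -0.31 on the 3 chips (camera adjusted p = 0.0251, 0.0295 with the chip as a block). The list was not called with an estimated correlation (camera adjusted p = 0.757 with an estimated correlation), and the range over 35 alternatives was 0.000157 to 0.757. Without DP wt number 3 the camera adjusted p was 0.388, and without DP cKO number 1 it was 0.195. None of the members passed over all probes; Aurkb (-1.60 ± 0.43, limma adjusted p = 0.338) and Ccne2 (-1.17 ± 0.33) passed when adjusted over the list alone. The other 23 lists were not called in DP. Interferon-stimulated genes, cholesterol synthesis, DP stage and SP maturation genes each had a camera adjusted p of 0.442, and B cell and sex-linked genes 0.480.

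In CD4 SP thymocytes, cholesterol synthesis genes, interferon-stimulated genes and cell cycle genes as groups were lower in cKO by camera with a preset correlation. All 3 calls were lost with an estimated correlation (camera adjusted p = 0.381, 0.381 and 0.445), in fry, and with the background level as a covariate (0.0963, 0.0963 and 0.231). Members with the smallest p were Dhcr7, the enzyme of the last step to cholesterol, Usp18, which removes the ubiquitin-like protein Isg15, and the mitotic kinase Plk1. The gene closest to the threshold was Itgae, the integrin chain that pairs with Itgb7 and binds E-cadherin on epithelium. It averaged 6.75 ± 0.28 in wt, where 3 of 3 arrays detected it, and 5.03 ± 0.21 in cKO, where none did. That is at least 3.27-fold (limma adjusted p = 0.0672, 0.133 with the chip as a block; 0.0276 with no filter and 0.0427 with the strict filter, within 0.0276 to 0.557 over 32 alternatives). Of 5 other Itgae probes 3 had the same sign. Wls averaged 6.58 ± 0.38 in cKO and 6.46 ± 0.17 in wt (0.12 ± 0.31, limma adjusted p = 0.965). The other tested Wls probes pointed the other way (5.71 in cKO against 5.78 in wt, and 4.98 against 5.27).

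No probe passed in CD4 SP. At an unadjusted p under 0.05 limma counted 2039 (1017 higher, 1022 lower), and 1 probe passed without CD4 SP cKO number 1. Genes higher in cKO that missed the threshold were Unc80 (1.53 ± 0.28, limma adjusted p = 0.144), St3gal5, which makes the ganglioside GM3 (1.24), Podn (1.64), Zfyve19 (1.13) and Ankrd36 (1.14). Lower were Ubxn11 (-1.70), Atp2b2 (-1.54), Plk1 (-1.18 ± 0.25, limma adjusted p = 0.267, 0.0129 with trend and robust variance, within 0.0129 to 0.660 over 32 alternatives) and Aim1 (-1.05).

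For cholesterol synthesis, 10 of 11 members were lower (median log2 -0.49) and the chip shifts were -0.61, -0.77 and -0.01 (camera adjusted p = 0.00864, 0.00964 with the chip as a block). Dhcr7 (-1.01 ± 0.37) and Sqle (-0.64) did not pass, over all probes or adjusted over the list alone. The camera adjusted p was 0.381 with an estimated correlation, 0.000283 to 0.381 over 35 alternatives, and 0.122 without CD4 SP cKO number 2. For interferon-stimulated genes, 23 of 29 were lower (median -0.28; chips -0.12, -0.44 and -0.22; camera adjusted p = 0.0235, 0.0285 with the chip as a block). Usp18 (-1.94 ± 0.57, limma adjusted p = 0.502) and Trim30a (-0.70) did not pass in either way. The list's camera adjusted p was 0.381 with an estimated correlation, 0.00163 to 0.381 over 35 alternatives, and 0.0634, 0.0567 and 0.301 without CD4 SP wt number 2, wt number 3 and cKO number 2. For the cell cycle, 22 of 29 were lower (median -0.17, or -0.15 with undetected members at their bounds; chips -0.37, -0.23 and -0.01; camera adjusted p = 0.0235, 0.0285 with the chip as a block). Of its members 3 passed adjusted over the list alone, including Plk1 and the survivin gene Birc5 (-1.01 ± 0.29), and 0 over all probes. The camera adjusted p was 0.445 with an estimated correlation and 0.00671 to 0.445 over 35 alternatives. It was 0.0659 without DP wt number 1, 0.136 without DP cKO number 2, 0.251 without CD4 SP wt number 1, 0.230 without CD4 SP wt number 2, 0.226 without CD4 SP cKO number 1, 0.0914 without CD8 SP wt number 2 and 0.0968 without CD8 SP cKO number 3. SP maturation genes, not called, had a camera adjusted p of 0.144, with 0.0193 to 0.647 over 35 alternatives, the lowest with median scaling. CD8 lineage genes, also not called, had 0.189, and 0.0419 without CD4 SP wt number 3.

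In CD8 SP thymocytes, CD8 lineage genes, interferon-stimulated genes and genes of double-negative thymocytes as groups were lower in cKO by camera with a preset correlation. All 3 calls were lost with an estimated correlation (camera adjusted p = 0.208, 0.396 and 0.396) and in fry, and that of interferon-stimulated genes also with the chip as a block (0.0504). The members with the smallest p were Prf1, the pore-forming protein of cytotoxic granules, Eomes, a transcription factor of cytotoxic cells, Xaf1 and Oasl2, both induced by interferon, and Kit, the receptor of stem cell factor. Wls averaged 6.31 ± 0.35 in cKO and 6.79 ± 0.17 in wt (-0.48 ± 0.31, limma adjusted p = 1). Another tested Wls probe was lower as well (5.59 in cKO against 5.92 in wt). A further Wls probe was higher (4.95 against 4.52), though no wt CD8 SP array detected it. No single probe passed. At an unadjusted p under 0.05 limma counted 1213 probes (592 higher, 621 lower), fewer than the 1333.8 that chance gives. Without CD8 SP cKO number 3, 1 probe passed. Genes that missed the threshold were Nfasc (1.36, limma adjusted p = 0.649), Vldlr (1.07), Zfp469 (1.25), Ulbp1, a ligand of an activating natural killer receptor (1.46), and Gtf2ird2 (1.67) among those higher. Map7 (-1.39), Ap2a2 (-1.99), Uchl4 (-1.37), Ccnt2 (-1.45) and Chchd10 (-1.70) were among those lower, each with a limma adjusted p of 0.715. Without CD8 SP cKO number 3 that of Ccnt2 was 0.0304, within 0.0304 to 1 over 32 alternatives.

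The 3 list calls in CD8 SP lay close to the threshold, each with a camera adjusted p of 0.0474, and 0 of their members passed over all probes or adjusted over the list alone. Of 9 CD8 lineage genes, 8 were lower (median -0.31; chips -0.36, -0.48 and -0.45; camera adjusted p = 0.0247 with the chip as a block), with Prf1 at -0.998 ± 0.337 and Eomes at -0.93. The list's camera adjusted p was 0.208 with an estimated correlation, and 0.00484 to 0.239 over 35 alternatives. Of 29 interferon-stimulated genes, 18 were lower (median -0.15, -0.13 with bounds), with Xaf1 at -1.60 ± 0.44 and Oasl2 at -1.28. The chips differed in sign (0.18, -0.64 and -0.22), and the call was lost with the chip as a block (camera adjusted p = 0.0504) and with an estimated correlation (0.396), within a range of 0.000487 to 0.705. Of 6 DN genes, 4 were lower (median -0.67, -0.51 with bounds; chips -0.48, -0.48 and -0.58; camera adjusted p = 0.0247 with the chip as a block), with Kit at -0.91 ± 0.33 and Erg at -0.98. The camera adjusted p was 0.396 with an estimated correlation, and 0.0105 to 0.583 over 35 alternatives. Without the 3 cKO arrays of number 3 all 3 calls ended (camera adjusted p = 0.102 for CD8 lineage and interferon, 0.549 for DN genes), and with the background level as a covariate the first 2 did (0.0678 each). Single arrays ended them as well. The CD8 lineage list had a camera adjusted p of 0.0581 without DP wt number 3, 0.0508 without DP cKO number 3, 0.0638 and 0.0558 without CD4 SP cKO number 1 and 3, 0.171 and 0.0904 without CD8 SP wt number 2 and 3, and 0.193 and 0.0678 without CD8 SP cKO number 2 and 3. The interferon list had 0.0555 and 0.0581 without DP wt number 1 and 3, 0.0508 without DP cKO number 3, 0.125 and 0.226 without CD4 SP cKO number 1 and 3, 0.705 and 0.0904 without CD8 SP wt number 2 and 3, and 0.382 and 0.0678 without CD8 SP cKO number 2 and 3. The DN list had 0.0597, 0.0542 and 0.0599 without DP wt number 1, 2 and 3, 0.0508 without DP cKO number 3, 0.0826 and 0.0558 without CD4 SP cKO number 1 and 3, 0.0874 and 0.468 without CD8 SP wt number 1 and 2, and 0.184 and 0.540 without CD8 SP cKO number 1 and 3.

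Over the mean of the 3 populations, interferon-stimulated genes, cholesterol synthesis genes, cell cycle genes and CD8 lineage genes were lower in cKO as groups by camera with a preset correlation. With an estimated correlation all 4 calls were lost (camera adjusted p = 0.288, 0.288, 0.567 and 0.288), as they were in fry. The interferon list included Gbp2, a GTPase that acts against pathogens in vacuoles, and the cholesterol list Sqle, an epoxidase of the sterol pathway. Wls stood at 0.18 ± 0.18 (limma adjusted p = 0.727). No probe passed, and limma counted 3138 at an unadjusted p under 0.05 (1666 higher, 1472 lower), or 2239 with genotype and label number as a random block. Without CD4 SP wt number 3, 3 probes passed. Genes that missed the threshold were Unc80 (0.99 ± 0.16), St3gal5 (0.86 ± 0.15), Ankrd22 (0.81), Dio2, which activates thyroid hormone (0.82), and V2r1 (0.92), all higher in each population. Lower in each were Pyroxd1 (-1.32 ± 0.24), Mtfr1l (-1.20), Mindy3 (-1.17), Fam111a (-1.07) and Zdhhc4 (-1.17). The lowest limma adjusted p was 0.126. Without the 3 cKO arrays of number 3, Unc80, Pyroxd1 and Zdhhc4 had 0.0495 and St3gal5 0.0491. The limma adjusted p over 31 alternatives reached 0.457 for Unc80, Pyroxd1 and St3gal5 and 0.484 for Zdhhc4.

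Of the interferon-stimulated genes, 21 of 29 were lower over the mean (median -0.17; chips 0.04, -0.46 and -0.17; camera adjusted p = 0.00355, 0.00627 with the chip as a block). Gbp2 was at -0.83 ± 0.27 and Usp18 at -0.85, and 0 passed adjusted over the list alone. The list's camera adjusted p was 0.288 with an estimated correlation, and 6.5e-05 to 0.288 over 34 alternatives. Of 11 cholesterol synthesis genes, 9 were lower (median -0.30, -0.17 with bounds; chips -0.46, -0.21 and -0.08; camera adjusted p = 0.00892, 0.00811 with the chip as a block). Sqle (-0.53 ± 0.16) and Dhcr7 (-0.70 ± 0.21) passed adjusted over the list alone. The camera adjusted p was 0.288 with an estimated correlation, 0.00176 to 0.288 over 34 alternatives, and 0.0571 without CD8 SP wt number 1. Of 29 cell cycle genes, 22 were lower (median -0.12; chips -0.24, -0.07 and -0.10; camera adjusted p = 0.00892, 0.0105 with the chip as a block), with Ccne2 at -0.55 and Top2a at -0.47 and 0 past adjusted over the list alone. The list's camera adjusted p was 0.567 with an estimated correlation, 0.00126 to 0.567 over 34 alternatives, and 0.0699 without DP wt number 3. Of 9 CD8 lineage genes, 7 were lower (median -0.29, -0.23 with bounds; chips -0.15, -0.41 and -0.17; camera adjusted p = 0.0241, 0.0265 with the chip as a block). Itgae (-0.56 ± 0.14) passed adjusted over the list alone, and Prf1 was at -0.48. By population Itgae was at 0.21 in DP, -1.72 in CD4 SP and -0.16 in CD8 SP. No wt DP array and no CD4 SP cKO array detected it. Its mean is thus not a fall shared by the populations, and no bound was applied to it. The list's camera adjusted p was 0.288 with an estimated correlation and 0.0072 to 0.288 over 34 alternatives. It was 0.215 without the 3 cKO arrays of number 3, 0.0871, 0.0742 and 0.0567 without DP wt number 1, DP wt number 2 and DP cKO number 3, and 0.268, 0.0655 and 0.0570 without CD4 SP wt number 2, CD4 SP cKO number 3 and CD8 SP wt number 3.

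**Figure D2:**
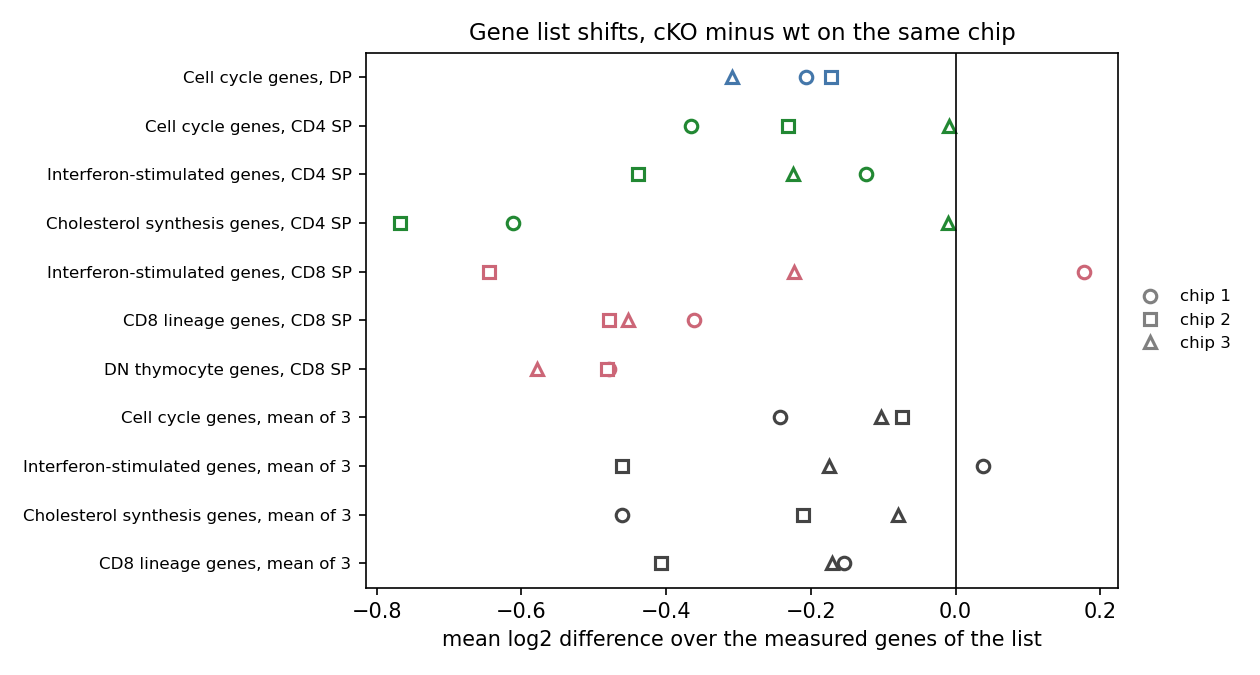
Mean log2 difference between the cKO and the wt array of the same chip over the measured genes of each list called in a genotype comparison. Each point is 1 of 3 chips, colours give the population, and 9 of the 11 calls, which fall on 5 different lists, were lower in cKO on all 3 chips, while interferon-stimulated genes were higher on chip 1 in CD8 SP (0.18) and over the mean (0.04).

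WNT target genes, such as Axin2 and Lef1, report WNT signalling in the cell that expresses them. They were not called in any genotype comparison (camera adjusted p = 0.739 in DP, 0.189 in CD4 SP, 0.701 in CD8 SP and 0.536 for the mean). None of the 15 measured members passed. The smallest p belonged to Bmp4 in DP (0.61), to Ephb2 (0.78 ± 0.28) and Axin2 (0.98 ± 0.45) in CD4 SP and to Ccnd1 (-0.57) in CD8 SP. In CD8 SP the median of the list was 0.04 and its mean -0.09. WNT secretion, receptor and signalling components had camera adjusted p-values of 0.705, 0.779, 0.578 and 0.947 in the same order.

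Lists of thymocyte stages and fates other than the CD8 lineage were also not called for the mean of the 3 populations. By camera the adjusted p was 0.511 for DP stage, 0.536 for positive selection, 0.512 for apoptosis and p53, 0.219 for SP maturation, 0.940 for CD4 lineage, 0.511 for regulatory T cells, 0.594 for NKT cells, 0.981 for gamma delta T cells and 0.700 for DN genes. For pathways it was 0.511 for the glucocorticoid response, 0.981 for immediate early genes, 0.536 for glycolysis and 0.536 for Notch targets. For other cell types it was 0.594 for thymic epithelium, 0.511 for macrophages and dendritic cells, 0.511 for B cells and 0.844 for erythroid cells, and for sex-linked genes 0.536. SP maturation had 0.0363 with median scaling, within a range of 0.0363 to 0.567 over 34 alternatives.

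The genotype difference itself did not pass as different between populations for any probe. In the limma F-test 1198 probes had an unadjusted p under 0.05. The lowest adjusted p, 0.793, belonged to Itgae, at 0.21 in DP, lower in cKO in CD4 SP and at -0.16 in CD8 SP. No wt DP array and no CD4 SP cKO array detected Itgae, so its differences in DP and CD4 SP rest partly on background. Next by p came the helicase Fbh1 (1.33, -0.37 and -0.73 in DP, CD4 SP and CD8 SP), Coq5 of ubiquinone synthesis (-1.26, 0.04 and 0.67) and Gtf2ird2 (-0.32, -1.05 and 1.67), then Frmpd4, Nfasc, Akr1b10 and Nudt8, each with a limma adjusted p of 0.982. No list passed as different between populations.

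Between wt CD4 SP and wt DP cells, genes of the DP stage and of division were lower in CD4 SP cells and genes of mature, mobile T cells were higher. Rag1, which cuts the receptor genes, Dntt, which adds nucleotides at the joints, and Endou fell. Il7r, the receptor for the survival cytokine IL-7, the homing receptor Ccr7 and the integrin chain Itgb7 rose, with interferon-stimulated genes such as Isg15. Of 1608 probes past the threshold in limma, 730 were higher and 878 lower, and 1666 passed with the chip as a block, 1543 of them shared. They stood for 1033 genes, 492 higher and 542 lower, with 1 gene called both ways by different probes. The largest rises were in Igfbp4 (at least 28.7-fold, limma adjusted p = 1.16e-07), Ifi27l2a (4.94 ± 0.25, limma adjusted p = 1.78e-09), Il7r (4.72 ± 0.27, limma adjusted p = 9.87e-09), Samhd1 (at least 22.2-fold, limma adjusted p = 2.8e-08) and Itgb7 (4.56 ± 0.23, limma adjusted p = 1.78e-09). The largest falls were in Endou (-5.14 ± 0.21, limma adjusted p = 2.02e-10), Ppp1r1c (-5.07 ± 0.38), Aqp11 (-4.85 ± 0.30), Rag1 (-4.64 ± 0.26, limma adjusted p = 7.06e-09) and Rapgef3 (-4.60 ± 0.35). Cd8b1 fell by 3.82 on the log2 scale, although 1 of its 2 other probes rose.

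DP stage genes fell in 11 of 13 members over all probes, and in 12 adjusted over the list alone (median -2.29, -2.21 with bounds; chips -2.64, -2.62 and -2.66; camera adjusted p = 6.68e-27). They included Rag1, Aqp11, Arpp21 (at least 15.9-fold) and Dntt (-4.12). Of 29 cell cycle genes, 15 fell and 0 rose, 20 adjusted over the list alone (median -1.31, -1.26 with bounds; camera adjusted p = 2.72e-22). Among them were the proliferation marker Mki67 (-2.56 ± 0.29), Top2a (-2.36), Kif11 (-2.23) and Rrm2 (-1.54). Of 29 interferon-stimulated genes, 19 rose, 21 adjusted over the list alone (median 1.32, 1.28 with bounds; camera adjusted p = 2.45e-20), such as Trim30a (3.44), Rsad2 (at least 4.73-fold) and Isg15 (1.88). Of 20 SP maturation genes, 12 rose, 14 adjusted over the list alone, where 1 fell (median 1.68, 1.43 with bounds; camera adjusted p = 6.9e-20), with Slfn1 (4.51) and Ccr7 (4.55) beside Itgb7 and Il7r. Of 16 positive selection genes, 9 rose, 11 adjusted over the list alone (median 1.00; camera adjusted p = 2.83e-10), among them Cd53 (3.32), Egr3 (at least 5.93-fold), Itm2a (3.15) and Egr2 (1.82).

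Of the CD4 lineage genes 3 of 5 rose, Tnfrsf4 (at least 6.16-fold), Cd40lg (at least 3.26-fold) and the costimulator Icos (1.84), and 4 rose and 1 fell adjusted over the list alone (median 1.84, 1.71 with bounds; camera adjusted p = 0.000237). Regulatory T cell genes rose in 4 of 9 members, among them Tnfrsf4, Tnfrsf18 (2.28) and Capg (at least 3.97-fold), and 4 rose and 1 fell adjusted over the list alone (median 0.56, 0.52 with bounds; camera adjusted p = 0.000584). Glycolysis genes rose in 3 of 11 members, among them Aldoa (1.28) and Pkm (1.08), and in 4 adjusted over the list alone (median 0.49; camera adjusted p = 0.00112, but adjusted p = 0.0633 with an estimated correlation, and 3.99e-05 to 0.0633 over 35 alternatives). Each of these 8 lists moved in the same direction on all 3 chips. Lists not called were NKT (camera adjusted p = 0.0580; Id2 rose by 3.89), CD8 lineage (0.767), WNT targets (0.953; Lef1 rose by 1.09, Bcl2l1 fell by 1.53), WNT components (0.770; Tle4 rose by 1.75), apoptosis (0.770; Bcl2 rose by 1.69, Fas fell by 2.08), glucocorticoid response (0.811; Dusp1 rose by 1.45, Fkbp5 fell by 2.18) and immediate early genes (0.811). The others were cholesterol synthesis (0.0677), gamma delta (0.381), Notch (0.811), DN (0.194), thymic epithelium (0.739), macrophages (0.811; Ctss rose at least 4.92-fold), B cells (0.0677; Ighm, whose probes may cross-hybridise with other immunoglobulin genes, fell by 1.82), erythroid (0.527) and sex-linked genes (0.641). Single arrays left out brought the camera adjusted p of 3 of these under the threshold. It was 0.0342 and 0.0370 for cholesterol synthesis without DP wt number 2 and CD4 SP cKO number 3, and 0.0465 for B cells without DP wt number 1. For NKT genes it was 0.0200, 0.0428, 0.0255 and 0.0280 without DP wt number 1, DP cKO number 1, CD4 SP wt number 2 and CD8 SP wt number 1. Among other settings, cholesterol synthesis had 0.0418 with only the arrays compared and 0.0310 without the 3 cKO arrays of number 3. B cells had 0.0381 without these 3 arrays and 0.0423 with the mean of all tested probes of a gene.

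Between wt CD8 SP and wt DP cells, genes of the DP stage also fell and genes of mature and of cytotoxic cells rose, while the cell cycle genes did not move as a group. Itgae rose with its partner Itgb7, and so did the granule protein gene Nkg7 and the chemokine Xcl1. The death receptor Fas and the semaphorin receptor Plxnd1 fell. Of 2231 probes past the threshold in limma, 769 were higher and 1462 lower, and 2365 passed with the chip as a block, 2126 of them shared. They stood for 1381 genes, 573 higher and 812 lower, with 4 called both ways. The count was 1226 without DP wt number 1, 1343 without DP wt number 2, 1369 without CD8 SP wt number 2 and 1381 without CD8 SP wt number 3. Median scaling moved the median difference of all probes to 0.21 and the share of higher probes from 34.5% to 47.4%. The largest rises were in Itgae (at least 26.3-fold, limma adjusted p = 2.15e-09), Itgb7 (4.25 ± 0.23, limma adjusted p = 6.62e-09), Ifi27l2a (4.07 ± 0.25), Xcl1 (at least 11.6-fold) and Nkg7 (at least 11.2-fold, limma adjusted p = 5.26e-08). The largest falls were in Plxnd1 (at least 11.5-fold, limma adjusted p = 2.33e-06), Arpp21 (-3.42 ± 0.29), the kinase Dyrk1b (-3.26 ± 0.50), Fas (at least 7.01-fold, limma adjusted p = 8.64e-05) and Tctex1d1 (at least 4.97-fold).

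DP stage genes fell in 9 of 13 members, 12 adjusted over the list alone (median -1.80; chips -1.66, -1.92 and -1.81; camera adjusted p = 3.04e-18), including Arpp21, Plxnd1, Ets2 (-1.80) and the repressor Bcl6 (-2.38). SP maturation genes rose in 10 of 20 members and 1 fell, 13 and 1 adjusted over the list alone (median 1.01, 0.93 with bounds; camera adjusted p = 6.75e-11), with Itgb7, Slfn1 (3.24), Il7r (3.20) and Ccr7 (3.47). Interferon-stimulated genes rose in 12 of 29, 13 with 1 fall adjusted over the list alone (median 0.76, 0.69 with bounds; camera adjusted p = 2.63e-08), with Ifi27l2a, Trim30a (2.79), Ifi47 (2.08) and Isg15 (1.45). Glycolysis genes rose in 6 of 11, also adjusted over the list alone (median 0.71; camera adjusted p = 7.68e-05), with Tpi1 (1.57), Pgam1 (1.11) and Aldoa (1.05). CD8 lineage genes rose in 4 of 9, 6 with 3 falls adjusted over the list alone (median 1.51, 1.08 with bounds; camera adjusted p = 0.00104), among them Itgae, Nkg7 and Xcl1.

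NKT and innate-like genes rose in 4 of 10 members, Nkg7 among them, while Slamf1 fell by 2.37 (median 0.94, 0.78 with bounds; 5 rose and 1 fell adjusted over the list alone). The list's camera adjusted p was 0.0160, with adjusted p = 0.0817 with an estimated correlation, 2.53e-05 to 0.107 over 35 alternatives and 0.0532 without DP wt number 2. DN genes rose in 1 of 6, and in 3 adjusted over the list alone (median 0.91, 0.73 with bounds). The camera adjusted p was 0.0226, with adjusted p = 0.136 with an estimated correlation, 0.00239 to 0.208 over 35 alternatives, 0.0532 without DP wt number 2 and 0.0971 without CD8 SP wt number 2. Of the 29 cell cycle genes, 18 lay higher and 11 lower (camera adjusted p = 0.513). Others not called were positive selection (0.371; Cd53 rose by 2.28), apoptosis (0.123; Bcl2l1 fell by 1.93), CD4 lineage (0.0903; Cd4 fell by 1.75), regulatory T cells (0.197), gamma delta (0.477), glucocorticoid response (0.168; Cdkn1b fell by 1.18), immediate early genes (0.399; Btg2 fell by 1.45), WNT targets (0.688; Myc rose at least 2.45-fold) and WNT components (0.745). The rest were cholesterol synthesis (0.363), Notch (0.153), thymic epithelium (0.546), macrophages (0.919), B cells (0.983), erythroid (0.688) and sex-linked genes (0.156). CD4 lineage genes had a camera adjusted p of 0.0339 with median scaling and 0.0355 with the mean of all tested probes of a gene.

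**Figure D3:**
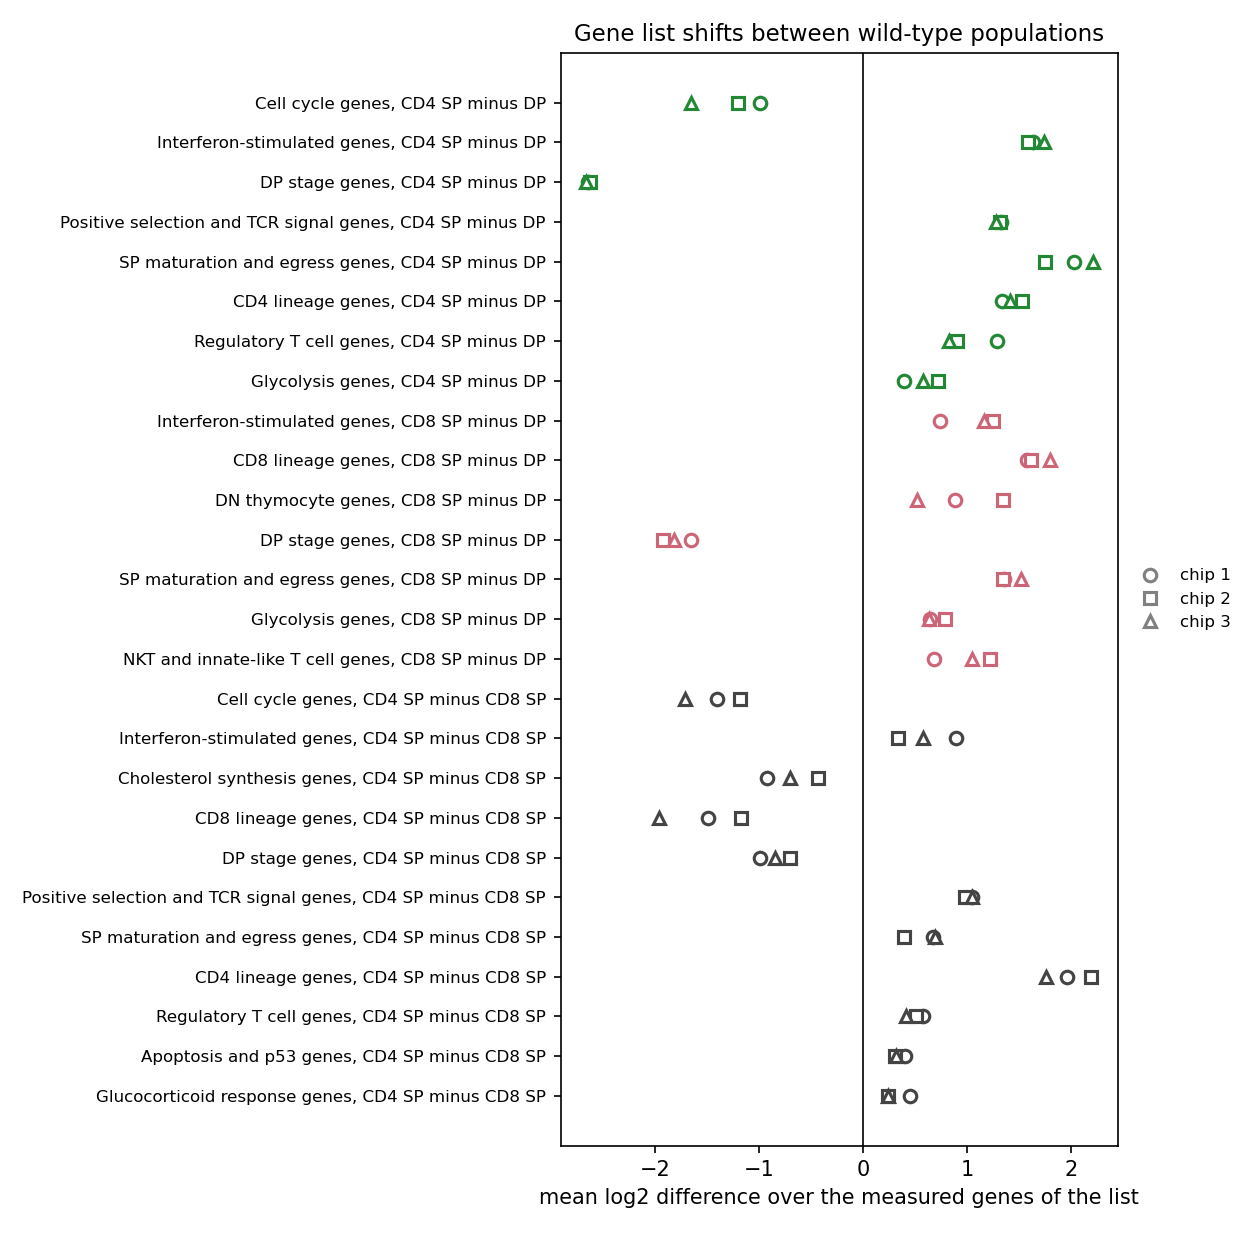
Mean log2 difference between wt populations on the same chip over the measured genes of each list called in a stage comparison. Each point is 1 of 3 chips and all 26 calls, on 14 different lists, moved in the same direction on the 3 chips; cell cycle genes lay at -1.40, -1.18 and -1.71 in CD4 SP minus CD8 SP.

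Between the 2 SP populations, wt CD4 SP cells had lower cell cycle genes than wt CD8 SP cells, and lower transcripts of the DP stage genes Rag1, Dntt, Aqp11 and Cxcr4. Lineage genes parted as the labels say, with Tnfrsf4 and Cd40lg, the ligand by which helper cells activate B cells, higher in CD4 SP and Nkg7, Itgae and Cd8b1 lower. Genes induced by T cell receptor signals, such as Itm2a and Egr2, were higher in CD4 SP cells. Of 912 probes past the threshold in limma, 473 were higher and 439 lower, and 920 passed with the chip as a block, 826 of them shared. They stood for 625 genes, 302 higher and 325 lower, with 2 called both ways. The count was 489 without CD4 SP wt number 1, 563 without CD4 SP wt number 2, 498 without CD8 SP wt number 1 and 515 without CD8 SP wt number 3. Median scaling moved the median difference of all probes to -0.12 and the share of higher probes from 51.9% to 39.2%. The largest rises were in the motor protein Myo6 (at least 18.8-fold, limma adjusted p = 1.73e-07), Tmem154 (3.63 ± 0.58), Itm2a (3.42 ± 0.42, limma adjusted p = 0.000169), Ptgir (at least 6.76-fold) and the cytokine Il21 (at least 6.52-fold, limma adjusted p = 1.19e-05). The largest falls were in Endou (-4.25 ± 0.21, limma adjusted p = 9.12e-09), Nkg7 (at least 10.8-fold, limma adjusted p = 3.82e-07), Rapgef3 (-3.56 ± 0.35), Nt5dc2 (-3.53 ± 0.32) and the mitotic kinase Aurka (-3.24 ± 0.46).

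Of 29 cell cycle genes, 19 fell and 0 rose, 24 adjusted over the list alone (median -1.42; chips -1.40, -1.18 and -1.71; camera adjusted p = 2.3e-27). They included Tyms, which makes thymidylate (-2.25 ± 0.29), Top2a (-2.26), Mki67 (-2.16) and Rrm2 (-1.54). CD4 lineage genes rose in 5 of 5, also adjusted over the list alone (median 2.19, 1.72 with bounds; camera adjusted p = 5.34e-11), with Tnfrsf4 (at least 5.87-fold) and Cd40lg (at least 3.29-fold). Positive selection genes rose in 5 of 16, 12 adjusted over the list alone (median 1.00; camera adjusted p = 3.54e-10), with Itm2a and Egr2 (1.44). CD8 lineage genes fell in 4 of 9, 5 adjusted over the list alone (median -1.47, -1.17 with bounds; camera adjusted p = 1.72e-07): Nkg7, Itgae (-2.81 ± 0.25), Cd8b1 (-3.05 ± 0.30) and Xcl1 (-2.09 ± 0.36, limma adjusted p = 0.00256, 0.0625 with only the arrays compared, within 6.57e-05 to 0.0625 over 32 alternatives). SP maturation genes rose in 4 of 20 and 1 fell, 7 and 1 adjusted over the list alone (median 0.54; camera adjusted p = 2.15e-06), with Il6ra (2.97) and Il7r (1.51). DP stage genes fell in 4 of 13 and 1 rose, 6 and 2 adjusted over the list alone (median -0.58; chips -0.99, -0.70 and -0.85; camera adjusted p = 9.88e-05): Aqp11 (-3.17 ± 0.30), Rag1 (-2.60 ± 0.26), Dntt (-2.99 ± 0.38) and Cxcr4 (-1.37 ± 0.26) had the smallest p.

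Interferon-stimulated genes were higher as a group (median 0.61; 1 member rose, 6 adjusted over the list alone; camera adjusted p = 7.58e-07), as were glucocorticoid response genes (median 0.53, 0.43 with bounds; 2 rose and 1 fell, 5 and 1 adjusted over the list alone; camera adjusted p = 0.00571) with Il7r, Dusp1 (1.75) and Fkbp5 (-2.38). Apoptosis and p53 genes were higher (median 0.32; camera adjusted p = 0.00334), with 0 members past over all probes and 3 adjusted over the list alone; Bcl2l11 (0.77) and Bcl2 (0.84) had the smallest p. Cholesterol synthesis genes fell in 3 of 11, 4 adjusted over the list alone (median -0.66, -0.34 with bounds; camera adjusted p = 0.00362), with Idi1 at -1.97 ± 0.27. That call had adjusted p = 0.0706 with an estimated correlation, 0.000766 to 0.0706 over 35 alternatives, and 0.0620 without CD8 SP wt number 1. Regulatory T cell genes were higher (median 0.39; 2 rose and 1 fell, also adjusted over the list alone; camera adjusted p = 0.0405), with Tnfrsf4 among them. This call had adjusted p = 0.0706 with an estimated correlation, 0.000239 to 0.188 over 35 alternatives, and 0.0627 with the chip as a block. Without CD4 SP wt number 1 or 2 it had 0.187 or 0.0765, and without CD8 SP wt number 1 or 3 it had 0.0742 or 0.0702. Not called were immediate early genes (0.336; Zfp36 rose by 1.33), NKT (0.720), WNT targets (0.721), WNT components (0.935), gamma delta (0.929), glycolysis (0.430; Tpi1 fell by 1.51), Notch (0.0964), DN (0.307), thymic epithelium (0.935), macrophages (0.954), B cells (0.0677; Ighm, with the same reserve on cross-hybridisation, fell by 2.15), erythroid (0.699) and sex-linked genes (0.411). Without DP cKO number 3 or CD8 SP wt number 3, B cell genes had a camera adjusted p of 0.0446 or 0.0384. It was 0.0395 with no filter and 0.0309 with genotype and number as a random block.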

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

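The fits without the 3 cKO arrays of number 3 and with the background level as a covariate were chosen after the arrays had been compared; the other alternatives were not. Counts of probes past the threshold that moved by over 1.5 times are given here with the array or setting that moved them; the cause was not tested. For cKO against wt in DP (1 probe in limma) the count was 0 with no background correction, with normexp, with median scaling, with the strict filter, with the series matrix values and with only the arrays compared. It was 11 with no filter, 5 with array weights and 2 without the 3 cKO arrays of number 3. Leaving out 1 array gave 0 to 2: 0 without DP wt number 1, 2 or 3 or DP cKO number 2 or 3, and 2 without DP cKO number 1. For CD4 SP (0 in limma, 2039 at an unadjusted p under 0.05) it was 4 with no filter, 1 with the strict filter, 2 with trend and robust variance, and 0 to 1 leaving out 1 array, with 1 without CD4 SP cKO number 1. For CD8 SP (0, unadjusted 1213) it was 1 with the covariate, and 0 to 1 leaving out 1 array, with 1 without CD8 SP cKO number 3. For the mean of the 3 populations (0, unadjusted 3138) it was 1 with no background correction, 2 with the series matrix values, 27 (4 higher, 23 lower) without the 3 cKO arrays of number 3, and 0 to 3 leaving out 1 array, with 3 without CD4 SP wt number 3. The interaction had 0 probes under every setting run (unadjusted 1198 in limma).

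For wt CD4 SP against wt CD8 SP (912) the count was 1718 with no background correction, 1376 with normexp, 1655 with the series matrix values, 1612 with trend and robust variance and 607 with only the arrays compared. Leaving out 1 array gave 489 to 949, with 489 and 563 without CD4 SP wt number 1 and 2, and 498 and 515 without CD8 SP wt number 1 and 3. For wt CD8 SP against wt DP (2231) it was 1209 with the covariate, and 1226 to 2313 leaving out 1 array, with 1226 and 1343 without DP wt number 1 and 2, and 1369 and 1381 without CD8 SP wt number 2 and 3. For wt CD4 SP against wt DP (1608) no setting moved it that far, and leaving out 1 array gave 1188 to 1654. The replicate block, which equals the chip as a block, gave 1 probe in DP, 0 in CD4 SP, CD8 SP and the mean, and 1666, 2365 and 920 between wt populations. With genotype and number as a random block these were 1, 0, 0 and 0, and 1910, 2839 and 1214, and the unadjusted count for the mean was 2239. With the covariate the share of higher probes was 43.6% for CD8 SP against DP and 37.7% for CD4 SP against CD8 SP.

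The 11 gene list calls for genotype became 7 with no filter, with the strict filter and without the 3 cKO arrays of number 3. They became 6 with the covariate, 5 with the mean of all tested probes of a gene, and 0 with an estimated correlation and with fry. With only the arrays compared, 3 of the 7 testable calls were kept, and the 4 calls for the mean of the 3 populations were not rerun. With the replicate block 10 of the 11 were kept, and with genotype and number as a random block 11. Leaving out 1 array gave 6 to 11, with 6 without DP wt number 3 and 7 without DP wt number 1, DP cKO number 3, CD4 SP cKO number 1, CD4 SP cKO number 3, CD8 SP wt number 2 or CD8 SP cKO number 3. The lists were lower in cKO under every setting run. For genes and lists without a call that stayed without one, a change of sign was not counted. Rsrp1 in DP (limma adjusted p = 0.168) had 0.0332 with no filter, within 0.0332 to 0.685 over 28 alternatives. Other probes reversed the sign of a named gene for wt CD4 SP against wt DP in Ppp1r1c (0.58), Cd8b1 (2.23, limma adjusted p = 0.00222) and Insig1 (0.073). They did so for wt CD8 SP against wt DP in Foxp3 (-0.70), Siglech (0.89) and the haemoglobin gene Hbb-b1 (-1.11, limma adjusted p = 0.0327, with a risk of cross-hybridisation between globin genes), and for wt CD4 SP against wt CD8 SP in Itgae (0.16), Cd8b1 (0.74) and Fdps (0.72). Signal over background limits dim genes, whose log2 differences depend on how background is treated, and where a group lay at background only a bound could be given.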

Other observations

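The tests of DP cells in the CD8 SP gate, of immature CD8 SP cells, and of background and sex for the cKO arrays of number 3 were chosen after the patterns had been seen. The tests of the lower lists against background and against the cKO arrays of number 3, and of the cell cycle list against background, were written before their results but use fits that were added after the arrays had been compared. Many genes also differed between the populations of cKO thymocytes. In cKO cells, 1261 probes passed in limma between CD4 SP and DP (557 higher, 704 lower), 1848 between CD8 SP and DP (730 higher, 1118 lower) and 1047 between CD4 SP and CD8 SP (477 higher, 570 lower). Rag1 fell from DP to CD4 SP by 4.52 on the log2 scale (limma adjusted p = 8.29e-09) and was lower in CD4 SP than in CD8 SP cells (-2.79 ± 0.26, limma adjusted p = 8.25e-06). Dntt (-4.00, limma adjusted p = 8.83e-06) and Aqp11 (-3.22, limma adjusted p = 7.13e-06) were also lower in cKO CD4 SP than in cKO CD8 SP cells, as were the proliferation genes Mki67 (-2.21, limma adjusted p = 0.00019), Top2a (-2.22, limma adjusted p = 0.000247) and Tyms (-1.79, limma adjusted p = 0.0013). Of 29 cell cycle genes, 20 fell in cKO CD4 SP against cKO CD8 SP (mean -1.64, camera adjusted p = 8.12e-33, 0.000329 with an estimated correlation). DP stage genes fell in 4 of 13 (mean -0.93, camera adjusted p = 0.000125, 0.0196 with an estimated correlation). Between cKO CD8 SP and cKO DP, cell cycle genes were higher (camera adjusted p = 0.00586, lost with an estimated correlation at 0.246), which was not called in wt (0.513). Apoptosis and p53 genes were called lower there in cKO (camera adjusted p = 0.0173, kept with an estimated correlation at 0.0406), but not in wt (0.123). NKT and DN genes were called there in wt (0.0160 and 0.0226) but not in cKO (0.271 and 0.803), and regulatory T cell genes between CD4 SP and CD8 SP in wt (0.0405) but not in cKO (0.258). These wt calls were lost with an estimated correlation (0.0817, 0.136 and 0.0706). Between CD4 SP and DP, cholesterol synthesis (camera adjusted p = 0.00245) and B cell genes (0.0294) were called lower in cKO but not in wt (0.0677 each). Both cKO calls were lost with an estimated correlation (0.0637 each). A test of whether these differences differ by genotype called 0 probes and no list (lowest camera adjusted p = 0.137, for cell cycle and DN genes in CD8 SP minus DP).

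Higher DP stage and cell cycle transcripts in wt CD8 SP than in wt CD4 SP cells have several possible explanations. DP cells in the CD8 SP gate, for the cell cycle part, were tested by mixing wt DP and wt CD4 SP levels gene by gene. The DP share was set to 28.2%, the upper 95% limit of what Bcl6 allows, the lowest among DP stage genes outside the pattern and detected on all wt CD8 SP arrays. Such a mixture lay at -0.58, -0.71 and -0.87 against DP on the 3 chips, and CD8 SP cells at 0.41, -0.02 and 0.05. The lowest excess over the mixture was 0.697 (standard deviation of the 3 excesses 0.156). This speaks against DP cells of the mean wt DP profile as the whole source, if the other cells have CD4 SP levels. In the same way, DP cells in the CD8 SP gate, for the DP stage part, would leave every one of the 13 genes with at least the share of its DP level that the genes of the pattern keep. The 4 genes higher in CD8 SP than in CD4 SP kept a median of 37.4% (Rag1 24.1%, Aqp11 30.2%, Dntt 44.7%, Cxcr4 55.0%), but 6 genes lay below that share by more than the 95% interval of their difference. One of the 6, Rag1, helps to set that median, which leaves 5 genes outside the pattern. These were Bcl6 at 17.7%, Arpp21 at 6.19%, and Plxnd1, Rag2 and Ccr9. No CD8 SP array detected the last 3, which were at least 11.5-fold, 3.88-fold and 3.85-fold below DP. Admixture of cells with the mean wt DP profile alone therefore does not account for the pattern. Both tests take DP cells in the gate to have that profile, so they cannot exclude DP cells with another profile. Immature CD8 SP cells that precede the DP stage remained open: the DN thymocyte list had a camera adjusted p of 0.307 between CD4 SP and CD8 SP, and such cells, known to divide, may contribute. The background level of the arrays did not account for the whole difference, since with it as a covariate the cell cycle list still stood at -1.48 (camera adjusted p = 9.23e-27, 0.00122 with an estimated correlation, 27 of 29 genes lower) against -1.43 without it.

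Lower interferon, cell cycle, cholesterol, CD8 lineage and DN lists in cKO could have a biological or a technical source. Brightness of the list genes alone did not explain them. Of 11 calls, on 5 different lists, 11 lay under the 5th percentile of 10000 random lists matched on mean log2 value. The random lists drew genes independently, so these percentiles do not allow for genes of a list that vary together. The lists had been picked as low in these same data, and the 4 calls for the mean are not independent of the others. The background level of the arrays, which cannot be parted from their overall intensity, remained open, with 6 of 11 calls kept when it was a covariate. The 3 calls in CD4 SP and those of CD8 lineage and interferon in CD8 SP were lost. The cKO arrays of number 3 also remained open, with 7 calls kept without these 3 arrays; the 3 calls in CD8 SP and that of CD8 lineage for the mean (camera adjusted p = 0.215) were lost. With an estimated correlation 0 calls were left, so the calls depend on how far the genes of a list are taken to vary independently.

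The cKO arrays of number 3 stood apart from the other cKO arrays in CD4 SP and CD8 SP on the first component of the residuals (18.1% of their variance). Scores of cKO number 1, 2 and 3 were -20.0, -32.2 and 52.2 in CD4 SP and -28.6, -34.0 and 62.6 in CD8 SP. In DP they were 7.64, -34.9 and 27.2, where number 2 lay farther from number 1 than number 3 did. That component correlated with the background level of the arrays (Pearson -0.878 over 18 arrays, Spearman -0.913, and Pearson -0.929 without DP cKO number 2 and 3). Shuffles of single arrays within groups gave a permutation p of 1e-05, the smallest that 100000 shuffles can give, and 0.00012 without these 2 arrays. They treat arrays of the same genotype and number as independent, which their residual correlations contradict. An exact test that kept such arrays together, added after these values were seen, gave p = 0.0278 with all arrays and without these 2. That is the smallest that 36 arrangements can give, and over both relations the adjusted p was 0.0556. Background that is low against the other cKO arrays may therefore be a mark of these arrays or share a cause with them. The evidence is limited by the few independent sets. In CD4 SP and CD8 SP number 3 lay within the wt range (175.8 against 156.2 to 177.3, and 198.6 against 186.0 to 235.1). There cKO number 1 and 2 lay above every wt array (219.1 and 236.6 in CD4 SP, 263.7 and 266.1 in CD8 SP). Genotype and background level were thus partly mixed. In DP number 3 lay below every wt array (126.5 against 141.7 to 183.4). Sex of the animals, read from Xist, gave a Pearson correlation of -0.653 (exact p = 0.472 with arrays kept together; permutation p = 0.0919 with shuffles within groups; 0.00355 with shuffles over all arrays, the scheme used first and changed after its result was seen; Spearman -0.439, permutation p = 0.201; -0.515 without CD4 SP cKO number 3 and CD8 SP cKO number 1, permutation p = 0.188). Xist was at 8.15, 7.77 and 7.42 in the cKO arrays of number 3 (DP, CD4 SP and CD8 SP), and the Y-linked Eif2s3y at 6.83, 7.05 and 7.28. In cKO number 1 and 2, Xist was at 9.25 and 9.19 in DP, 9.17 and 8.78 in CD4 SP, and 8.75 and 7.88 in CD8 SP. Eif2s3y was there at 4.75 and 6.68, 5.18 and 6.07, and 5.69 and 5.09. By the probes that stand for these genes, number 3 thus had the lowest Xist and the highest Eif2s3y of the cKO arrays in each population. A dimmer Xist probe was instead highest in number 3 in CD4 SP (6.41 against 5.31 and 4.50) and in CD8 SP (6.79 against 6.12 and 4.62). The remaining tested Xist probes were lowest in number 3 in each population. Over the wt arrays Xist ran from 8.33 to 9.32 and Eif2s3y from 5.21 to 7.28. Both were present in cKO number 3, but also on wt arrays such as DP wt number 3 (Xist 9.06, Eif2s3y 7.28), so this does not set number 3 apart. The part of sex could not be settled.

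Splits of the same arrays were counted for each comparison. With 6 arrays there are 10 splits of 3 against 3, too few for a share under 0.05. For DP, 3 of the 10 had 1 probe or more. The highest of the others had 8, with DP wt number 1, DP wt number 2 and DP cKO number 3 on one side. This points to a structure of these samples apart from genotype. Those 3 arrays had the lowest background levels in DP (154, 142 and 126). DP wt number 3 and DP cKO number 1 and 2 had 183, 174 and 221. For CD4 SP and CD8 SP all 10 of 10 had as many as the real 0, as any split must, so this tests nothing; the highest in the others were 2 and 0. For the wt populations only the real split (1 of 10) had as many: 1608 against at most 1 for CD4 SP and DP, 2231 against at most 5 for CD8 SP and DP, and 912 against 0 for CD4 SP and CD8 SP. Of 100 drawn groupings, 100 had as many probes as the real 0 for the mean of the 3 populations (highest 4) and 100 for the interaction (highest 9), which any grouping must and which therefore also tests nothing. For the genotype lists 1 of 100, the real one, had as many calls as the real 11, with at most 6 in the others. These groupings break up arrays of the same genotype and number, whose residuals correlate, so that share overstates how rare 11 calls are. With such arrays kept together, a count added after the drawn groupings were seen, there are 10 groupings, too few for a share under 0.05, and the highest of the others had 4 list calls. One of these, cKO number 1 and 2 with wt number 3 against the rest, had 40 probes for the mean of the 3 populations. The real one had 0, which points to a structure of the samples apart from genotype. That grouping put together the arrays with the highest background levels in DP and CD4 SP, but not in CD8 SP. Of the 99 other drawn groupings, 81 gave at least 1 list call (median 2), so camera with the preset correlation calls lists in most arbitrary groupings of these arrays, and single list calls carry little weight.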
